A study of Homo sapiens with 6 samples.

How the data were processed

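Total RNA was isolated from senescent (PDL 63) and young (PDL 28) MRC5 fibroblasts with TRIzol, per the labels' protocols. Per the same protocols, 40 µg was reverse transcribed with aminoallyl-dUTP and coupled to Cy5 or Cy3. Channel 1 was Cy5 and channel 2 Cy3 on each of the 6 arrays, which form 3 biological replicates with a technical dye swap each, per the labels and the series' design text. Nothing says that the biological replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Which primer was used, the scanner, the image analysis, the background correction, the filter and the normalization are not given in the sources used here.

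The deposited table holds 1 value per probe and array, 21794 probes on 6 arrays with 0 missing values. Its scale and centring were read from the values: the deposited values are log2 ratios, because the commonest values of an array are parted by the log2 of ratios of small whole numbers, and each array has a median of 0. They were deposited without turning the dye-swapped arrays, because arrays of the same orientation correlated above 0 and most pairs of opposite orientation below 0; the arrays of the replicate 3 swap had a Pearson coefficient of 0.0857 over probes as deposited. The direction, channel 1 over channel 2, was taken from the order in the titles and is likely, not stated. Any other normalization of the deposited values stays unknown, and without intensities, signal over background could not be computed. SDs of the arrays ranged from 0.481 to 1.01 on the log2 scale.

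Probes were named through the platform annotation, which listed 17509 of them: 17434 had 1 gene, 75 had several and 4285 of the table's probes had none. Entrez identifiers of 17409 probes matched the RefSeq gene table of GRCh38.p14, and 0 symbols needed an update. Probes naming 1 gene were averaged to 15239 genes, 1814 of them with more than 1 probe (at most 17). No coordinates are given, since no build is named for the array.

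Each array with senescent RNA in Cy3 had its sign turned, the arrays of a swap were averaged, and the 3 replicate values were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, 2 residual and 3.03 prior degrees of freedom). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes (21 of biology and 6 of cell type markers) were tested with camera at a preset correlation of 0.01, with its estimated correlation and with fry, and their members were also adjusted over the list alone. The dye effect was fitted over 6 arrays with the replicate as a random block (duplicateCorrelation). The groups, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

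The text names the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with 1 sign on all 6 arrays, up to 4 members of each list past the threshold with the largest change, and a fixed set of genes of senescence and of fibroblasts; 2 genes of that set and 1 of the gene lists are not reported here. Other genes of the lists (RBL1, H1-2, HMGA2, LMNB2, EZH2, COL11A1, SPP1) and the histone genes of the closing section were chosen after their values were seen. Alternatives were other centring, scaling and quantile normalization, other treatments of the dye swap, single orientations, robust eBayes, other rules for several probes, other thresholds, an unmoderated test, leaving out noisy probes and leaving out each replicate. Leaving out dim probes was added after seeing the data. They were 4183 probes that, on any array, matched the log2 ratio of whole numbers up to 20 within 0.00011. The array's commonest value was subtracted before matching. Per array, 5.07% to 6% of probes matched, against 1.29% to 1.66% at a shifted control. Some matches are thus by chance, and no intensities were available to show that these probes were dim.

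The scripts were tested on simulated data for 15239 genes. With 200 changed genes, 2%, 90%, 100% and 100% were recovered at log2 changes of 0.5, 1, 2 and 3, and 20 of 166 calls were false (12%, above the nominal rate). With 2000 changed genes, 52.8%, 96.2%, 99.8% and 100% were recovered and 4.75% of calls were false. A simulated list of 50 genes shifted by 0.5 was called with the preset correlation and not with the estimated one, and 0 unshifted lists were called. In the real data the estimated correlation reached 0.612 (mitosis list) and 0.571 (DNA replication list), above the preset of 0.01. The simulated genes were independent. How often the preset test makes false calls at such correlations, or the estimated one misses shifts, was not tested. Figures were drawn with matplotlib 3.10.9.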

Results

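RNA from MRC5 cells, fibroblasts from human fetal lung, was compared between a late and an early passage on 2-colour arrays. Senescent cells had reached population doubling level (PDL) 63, where dividing cell cultures enter replicative senescence, a lasting arrest of division. Young cells were at PDL 28. Each of 6 arrays held both RNAs, 1 in Cy5 and the other in Cy3, as 3 biological replicates with a dye swap each. Every array gave a value for all 21794 probes, and 15239 genes were measured by probes naming 1 gene. The comparison asks which transcripts differ between senescent and young fibroblasts. Values are log2 ratios of senescent over young, given as mean ± SD over the 3 replicates, each the mean of its dye-swap pair.

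Senescent cells had higher levels of WNT16, a secreted Wnt ligand, by 2.40 ± 0.63 (SD, n = 3) on the log2 scale, and of the matrix metalloproteinases MMP3 (2.30 ± 0.67) and MMP1 (1.74 ± 0.11). CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose by 1.70 ± 0.28. The protease inhibitor gene A2M was lowest against young cells, at -2.93 ± 0.44, followed by the hyaluronan-degrading protein gene CEMIP (-2.82 ± 0.49). The mitotic kinase gene CDK1 fell by 2.08 ± 0.43, and TOP2A, the DNA topoisomerase of dividing cells, fell by 1.85 ± 0.36. In all, 1012 of 15239 genes passed (limma, adjusted p under 0.05), 416 higher and 596 lower in senescent cells. Of these, 358 differed at least 2-fold, 92 higher and 266 lower, and 977 had 1 sign on all 6 arrays. The direction is the likely one: it rests on the order of the RNAs in the array titles, read as channel 1 over channel 2, because no source used here states which channel was divided by which. It was also checked by a rule fixed in advance, that the mitosis list should be lower in senescent cells, so that list's direction is not independent evidence.

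The smallest adjusted p was 0.0241, and the count depended on every replicate. Without replicate 1 or without replicate 2, 0 genes passed in limma (2464 and 3743 at an unadjusted p under 0.05). Without replicate 3, 375 passed (3637 at an unadjusted p under 0.05), 287 of them among the 1012. All 1012 kept their sign in each of these fits, which share replicates with the main fit. Each fit has fewer replicates, and whether that alone lowers the count was not tested. With all 6 arrays, a dye term and the replicate block, 2470 genes passed. That fit takes both arrays of a dye swap as separate observations, with a single block correlation of -0.134 for all genes. Its larger counts, here and below, thus do not rest on more biological replicates. The number of arrays limits the precision of every value given here.

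The other genes with the largest changes were of varied function. Among those that rose were H2AC6 (2.26 ± 0.45), a histone H2A gene, ZNF440 (2.11 ± 0.77), a zinc finger gene, TSPAN13 (2.08 ± 0.06), a tetraspanin, and DCBLD2 (1.98 ± 0.20), a membrane receptor. PLCB4, a phospholipase C gene, rose by 1.90 ± 0.24, and KRTAP1-5, a keratin-associated protein gene of hair, rose by 1.89 ± 0.49. CYTL1 (1.84 ± 0.55), a secreted cytokine-like protein gene, and DNAI3 (1.82 ± 0.44), a dynein chain gene, completed the 10 largest increases. Among those that fell were ADGRG6 (-2.66 ± 0.60), an adhesion G-protein-coupled receptor, and SPRY1 (-2.60 ± 0.33), an inhibitor of growth factor signalling. IGFBP5, a binding protein of insulin-like growth factors, was at -2.50 ± 0.94, and its probes gave -3.06 and -1.93. CDCA7 (-2.47 ± 0.45), FGL2 (-2.46 ± 0.32), the histone gene H4C3 (-2.43 ± 0.80), CSRP2 (-2.34 ± 0.38) and COL15A1 (-2.30 ± 0.55) made up the rest of the 10 largest decreases. With arrays scaled to one spread ZNF440 (limma adjusted p = 0.052) and IGFBP5 (0.0517) lost their call.

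**Figure D1:**
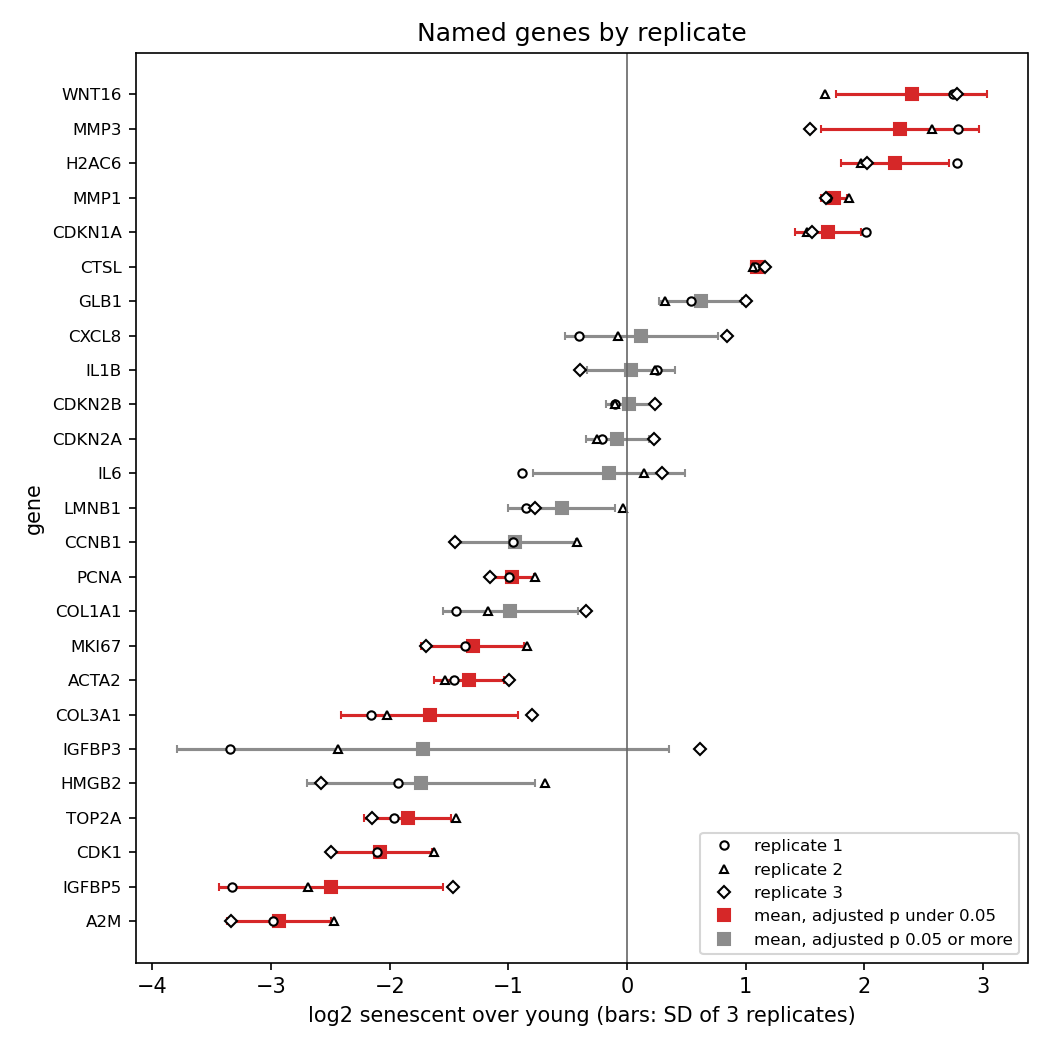
Log2 ratio of senescent over young cells (x axis) for named genes (y axis). Open symbols are the 3 replicates, squares are means and bars are SD; red squares mark genes with an adjusted p under 0.05. CDKN1A, MMP1 and MMP3 lie above 0 in every replicate and CDK1, TOP2A and A2M below 0, whereas CDKN2A (-0.08), IL6 (-0.15) and CXCL8 (0.12) lie near 0, and IGFBP3 has replicates on both sides of 0.

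Genes of mitosis fell together. Of 60 measured genes of the mitosis list, 36 fell, 0 rose and 24 did not pass; adjusted over the list alone, 51 fell and 0 rose. The condensin gene SMC4 fell by 1.92 ± 0.41, the spindle gene ASPM by 1.91 ± 0.71 and the cyclin gene CCNA2 by 1.89 ± 0.72. The proliferation marker MKI67 fell by 1.30 ± 0.43, while the cyclin gene CCNB1 was at -0.94 ± 0.51 and did not pass (adjusted p = 0.065). The median of the list was -1.17, and as a set it was lower than other genes (camera with a preset correlation, adjusted p = 2.32e-22; adjusted p = 0.6 with an estimated correlation). On single arrays the median ranged from -1.94 to -0.744. Without replicate 3, 17 genes of this list passed, all of them lower, and with the replicate block 48 did.

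DNA replication genes went the same way. Of 56 measured genes, 24 fell, 0 rose and 32 did not pass; adjusted over the list alone, 43 fell and 1 rose. Examples were MCM3, a subunit of the replicative helicase (-1.51 ± 0.30), RFC4 of the clamp loader (-1.48 ± 0.53), GMNN, an inhibitor of origin licensing (-1.41 ± 0.47), and the primase gene PRIM1 (-1.40 ± 0.54). PCNA, the sliding clamp, fell by 0.97 ± 0.19. The list's median was -0.875 (camera adjusted p = 1.84e-17; adjusted p = 0.6 with an estimated correlation). Without replicate 3, 5 of its genes fell, and with the replicate block 41 did.

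For DNA repair, 10 of 37 measured genes fell, 0 rose and 27 did not pass, with a median of -0.471; adjusted over the list alone, 16 fell and 0 rose. The exonuclease gene EXO1 fell by 1.53 ± 0.45, TOPBP1 by 1.13 ± 0.42, and RAD54L and H2AX, both acting at double-strand breaks, by 1.12 ± 0.21 and 1.06 ± 0.23. The set was lower than other genes (camera adjusted p = 9.54e-08; adjusted p = 0.6 with an estimated correlation). Among 39 genes of splicing and RNA processing, 5 fell, 0 rose and 34 did not pass, with a median of -0.464; adjusted over the list alone, 21 fell and 1 rose. SNRPD1, a core protein of spliceosomal particles, fell by 0.89 ± 0.34, HNRNPA1 by 0.87 ± 0.29, HNRNPH3 by 0.82 ± 0.30 and PTBP1, a splicing repressor, by 0.70 ± 0.22. Camera gave an adjusted p of 1.47e-08 for this list, with adjusted p = 0.6 with an estimated correlation. Without replicate 3, 2 repair genes and 0 splicing genes fell; with the replicate block 15 and 18 did, and 1 splicing gene rose.

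Regulators of the G1 phase went both ways. Of 14 measured genes in the list of kinase inhibitors and their partners, 2 rose, 3 fell and 9 did not pass; adjusted over the list alone, 3 rose and 6 fell. CDKN1A rose (adjusted p = 0.0286), as did the cyclin gene CCND2 (1.70 ± 0.44). CDKN1B, encoding the inhibitor p27, fell by 1.28 ± 0.20 and the kinase gene CDK4 by 0.96 ± 0.22; RBL1, a relative of RB1, was the third that fell (-0.91). CDKN2A, the source of the p16 inhibitor, was at -0.08 ± 0.27 (adjusted p = 0.729), and CDKN2B at 0.01 ± 0.20. RB1 was at -0.60 ± 0.31 and did not pass. The list as a set was not called (median -0.14, camera adjusted p = 0.261).

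The list of chromatin and nuclear lamina genes had 5 of 35 measured genes higher, 12 lower and 18 that did not pass; adjusted over the list alone, 5 rose and 23 fell. Those that rose included H2AC6 and the histone gene H2BC21 (1.66 ± 0.60), whose 17 probes gave 1.15 to 2.14, with H1-2 (1.38), a linker histone gene, and HMGA2 (1.49). Those that fell included H4C3 and LBR, the lamin B receptor (-1.57 ± 0.28), together with LMNB2 (-1.20), a B-type lamin gene, and EZH2 (-0.83), which encodes a histone methyltransferase. LMNB1, a lamin often low in senescent cells, was at -0.55 ± 0.45 (adjusted p = 0.145), and the chromatin protein gene HMGB2 at -1.73 ± 0.96 (adjusted p = 0.0582). The median was -0.552 (camera adjusted p = 1.2e-05; adjusted p = 0.6 with an estimated correlation). Without replicate 3, 3 of these genes rose and 4 fell, and with the replicate block 5 rose and 18 fell.

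Cytokine genes of the senescence-associated secretory phenotype, the set of factors that senescent cells release, showed little shift. Of 39 measured genes, 1 rose, 2 fell and 36 did not pass, with a median of -0.03; adjusted over the list alone, 3 rose and 3 fell. The decoy receptor gene TNFRSF10C rose by 1.31 ± 0.60, while the chemokine gene CCL2 fell by 1.40 ± 0.46 and TNFAIP6, a hyaluronan-binding protein gene, by 1.38 ± 0.42. IL6 was at -0.15 ± 0.64 (adjusted p = 0.727), CXCL8 at 0.12 ± 0.64 (adjusted p = 0.784) and IL1B at 0.03 ± 0.37 (adjusted p = 0.911). Camera gave an adjusted p of 0.76 for the list. The median was -0.15 without replicate 3, -0.178 on the arrays with senescent RNA in Cy5 and 0.0824 on those with it in Cy3. The list was called in none of these (camera adjusted p = 0.161, 0.215 and 0.95).

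Proteases and their inhibitors changed in both directions. Of 32 measured genes, 4 rose, 7 fell and 21 did not pass; adjusted over the list alone, 9 rose and 7 fell. MMP3 and MMP1 rose, whereas the cysteine protease gene CTSK fell by 1.53 ± 0.37 and PCOLCE, an enhancer of procollagen processing, by 1.23 ± 0.22 (camera adjusted p = 0.721). With arrays scaled to one spread 6 of the list rose and 3 fell, and with quantile normalization 7 rose and 6 fell. Growth factors and their binding proteins had 6 of 47 higher, 6 lower and 35 that did not pass; adjusted over the list alone, 11 rose and 12 fell (camera adjusted p = 0.607). The hormone gene STC1 rose by 1.42 ± 0.03, IGFBP7 by 1.38 ± 0.65 (adjusted p = 0.0701 with arrays scaled to one spread and 0.0509 with quantile normalization) and the growth factor gene NRG1 by 1.28 ± 0.58. IGFBP3 was at -1.72 ± 2.07 and did not pass (adjusted p = 0.212), with replicates at -3.34, -2.44 and 0.61.

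Extracellular matrix genes had a median of -0.153 and were lower as a set (camera adjusted p = 0.00878; adjusted p = 0.643 with an estimated correlation). The replicate medians were -0.327, -0.273 and -0.0042; without replicate 3 the median was -0.304, and 17 genes fell. Of 59 measured genes, 2 rose, 9 fell and 48 did not pass; adjusted over the list alone, 4 rose and 18 fell. Beside COL15A1, the proteoglycan gene VCAN fell by 1.90 ± 0.65, TNC by 1.67 ± 0.53, with probes at -2.36 and -0.98, and the fibrillar collagen gene COL3A1 by 1.66 ± 0.75. COL3A1 lost its call with arrays scaled to one spread (adjusted p = 0.0745) and with quantile normalization (0.0507). COL1A1 was at -0.98 ± 0.57 and did not pass (adjusted p = 0.0702), and COL11A1 (0.78) and SPP1 (0.66) were the genes that rose. Contractile genes had 5 of 30 lower, 0 higher and 25 that did not pass; adjusted over the list alone, 8 fell and 1 rose. They included the non-muscle myosin gene MYH10 (-1.37 ± 0.33), smooth muscle actin ACTA2 (-1.33 ± 0.29), CNN2 (-0.82 ± 0.14) and LMOD1 (-0.77 ± 0.19). ACTA2 lost its call with arrays scaled to one spread (adjusted p = 0.0537). Their median was -0.282 (camera adjusted p = 0.000652; adjusted p = 0.6 with an estimated correlation), and -0.478 without replicate 3. On the arrays with senescent RNA in Cy5 alone, neither list was called: the matrix median was -0.137 (camera adjusted p = 0.0857) and the contractile median -0.205 (0.0702). On the Cy3 arrays both were called lower, at -0.298 (camera adjusted p = 0.00137) and -0.45 (1.79e-05).

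**Figure D2:**
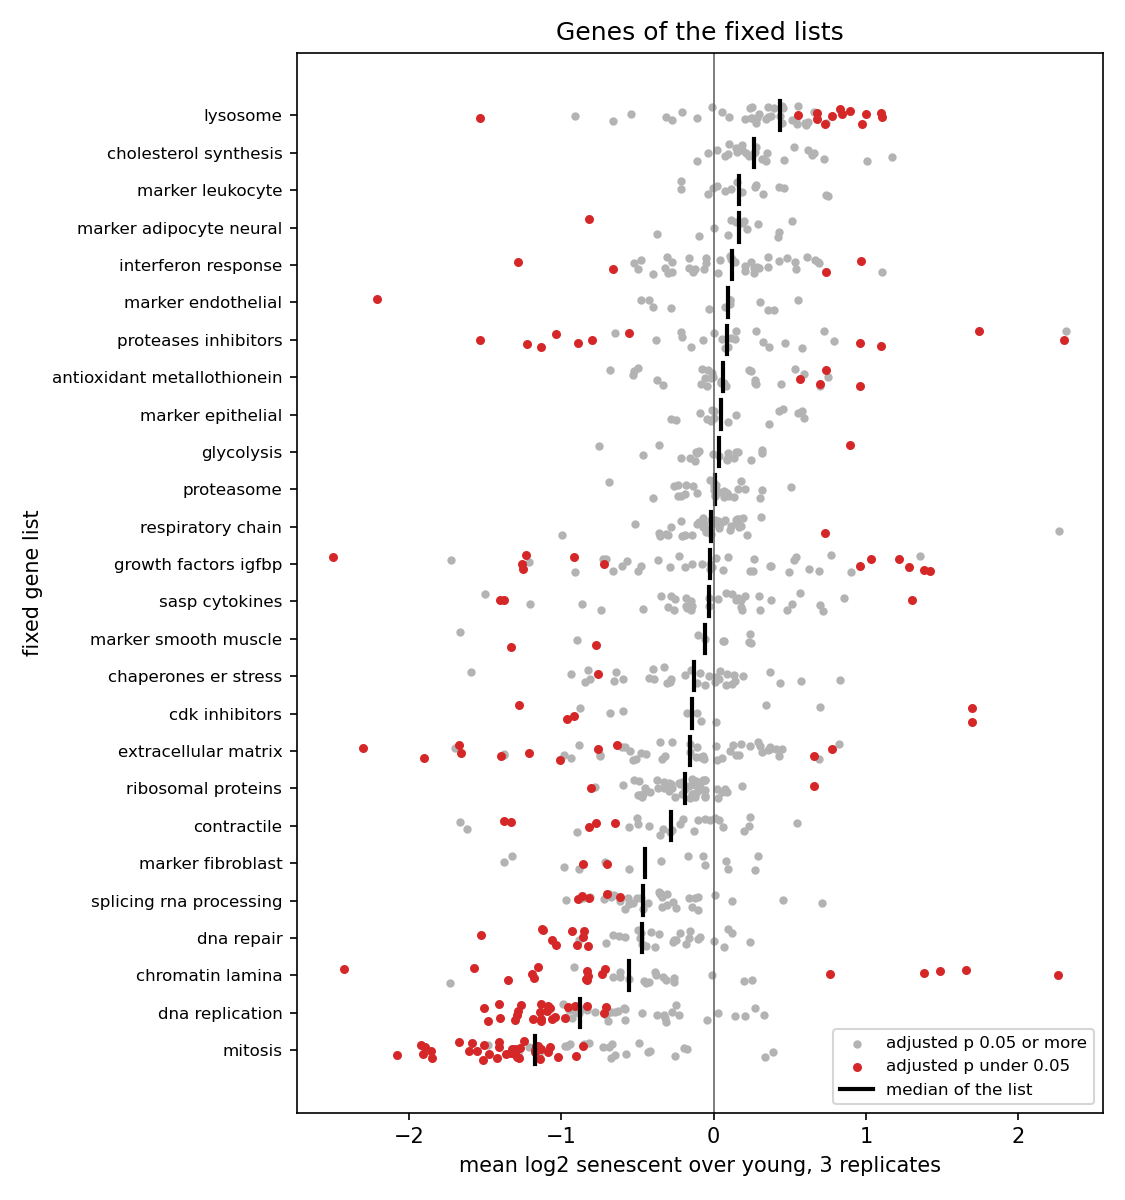
Mean log2 ratio of senescent over young cells (x axis) for the measured genes of the fixed lists reported here (y axis, ordered by median). Points are genes, red where the adjusted p is under 0.05, and black bars are list medians. The medians run from -1.17 for mitosis to 0.435 for lysosome genes, and the cytokine list is centred near 0.

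Lysosomal genes rose more often than they fell. Of 49 measured genes, 12 rose, 1 fell and 36 did not pass; adjusted over the list alone, 27 rose and 5 fell. The cathepsin gene CTSL rose by 1.10 ± 0.05, GM2A, a cofactor of ganglioside breakdown, by 0.999 ± 0.295, and CTSH by 1.11 ± 0.46, although CTSH had that sign on only 4 of the 6 arrays and lost its call with the replicate block (adjusted p = 0.165) and with arrays scaled to one spread (0.0546). The cathepsin gene that fell was CTSK. GLB1, the gene of the lysosomal beta-galactosidase, was at 0.62 ± 0.35 and did not pass (adjusted p = 0.0853). The median was 0.435 (camera adjusted p = 2.61e-07; adjusted p = 0.6 with an estimated correlation). Without replicate 3, 3 rose and 2 fell, and with the replicate block 21 rose and 3 fell. The median was 0.564 on the arrays with senescent RNA in Cy5 and 0.253 on those with it in Cy3. Cholesterol synthesis genes were higher as a set, with a median of 0.263 (camera adjusted p = 0.00111; adjusted p = 0.6 with an estimated correlation), although 0 of 27 passed singly, and 0 did adjusted over the list alone. With the replicate block 5 rose and 0 fell, and scaling, quantile normalization and leaving out noisy or dim probes gave the same counts. The replicate medians were 0.174, 0.179 and 0.641, and without replicate 3 the median was 0.134 (camera adjusted p = 0.0494).

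Ribosomal protein genes had a median of -0.186 and were lower as a set (camera adjusted p = 0.000141; adjusted p = 0.6 with an estimated correlation). Of 49, RPS9 fell (-0.81 ± 0.27), RPS29 rose (0.66 ± 0.16) and 47 did not pass; adjusted over the list alone, 0 passed. The median was -0.111 without replicate 3, and -0.0709 on the arrays with senescent RNA in Cy5, where the set was not called (camera adjusted p = 0.131). Genes of antioxidant defence and metallothioneins had 4 of 32 higher and 0 lower, with 28 that did not pass; adjusted over the list alone, 9 rose and 2 fell. They were GSTM1 (0.96 ± 0.27), the mitochondrial superoxide dismutase gene SOD2 (0.74 ± 0.04), the metallothionein gene MT2A (0.70 ± 0.02) and GSS (0.57 ± 0.07). The 3 probes of SOD2 gave 0.243 to 1.003. The set was not called (camera adjusted p = 0.1). It was called higher with the replicate block (camera adjusted p = 0.0195), with the arrays as independent (0.0196), on the Cy5 arrays alone (0.00235), with robust empirical Bayes (0.0464) and without replicate 3 (0.0106). Interferon response genes had 2 of 46 higher, 2 lower and 42 that did not pass; adjusted over the list alone, 5 rose and 2 fell (camera adjusted p = 0.28). RIGI, a sensor of viral RNA, rose by 0.97 ± 0.19 and SP100 by 0.74 ± 0.06, while USP18 fell by 0.66 ± 0.19. The even split changed to 6 higher and 2 lower with arrays scaled to one spread, 8 and 2 with quantile normalization and without noisy or dim probes, and 6 and 3 with the replicate block. The immunoproteasome gene PSMB10 was at -1.29 ± 0.32 but had that sign on only 4 of the 6 arrays, its mean was 1.25 on the arrays with senescent RNA in Cy3, and it lost its call with the replicate block (adjusted p = 0.33).

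The remaining metabolic lists were not called as sets over the 3 replicates. Among 36 chaperone and endoplasmic reticulum stress genes, CCT2 fell (-0.76 ± 0.27) and 35 did not pass (camera adjusted p = 0.084). HK1, a hexokinase gene, rose by 0.90 ± 0.23 among 21 glycolysis genes (camera adjusted p = 0.969). NDUFC2 rose by 0.73 ± 0.13 among 45 respiratory chain genes (camera adjusted p = 0.914), and 0 of 31 proteasome genes passed (camera adjusted p = 0.969). Adjusted over the list alone, 1 glycolysis gene rose and 0 genes of the chaperone, respiratory chain and proteasome lists passed. For the respiratory chain the median was -0.0167 and the mean 0.0165, and for the proteasome 0.0107 and -0.0131, so that median and mean differed in sign. The proteasome list was called higher on the arrays with senescent RNA in Cy5 (median 0.233, camera adjusted p = 0.0046) and lower on those with it in Cy3 (-0.183, 0.0322). The chaperone list was called lower on the Cy3 arrays (camera adjusted p = 0.00184) and without replicate 3 (0.00102).

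Among markers of fibroblasts, of 16 measured genes, 2 fell, 0 rose and 14 did not pass, and adjusted over the list alone 6 fell and 0 rose. The platelet-derived growth factor receptor genes PDGFRA (-0.85 ± 0.12, with probes at -1.48 and -0.23) and PDGFRB (-0.70 ± 0.19) were those that fell. PDGFRB lost its call with arrays scaled to one spread (adjusted p = 0.0836) and with quantile normalization (0.0531). The median was -0.449 (camera adjusted p = 0.00484; adjusted p = 0.6 with an estimated correlation), and the set was not called on the Cy5 arrays alone (-0.22, camera adjusted p = 0.102). Marker lists of other cell types were not called as sets over the 3 replicates. Leukocyte markers were called higher on the Cy3 arrays (median 0.431, camera adjusted p = 0.00414), without replicate 2 (0.0404) and without replicate 3 (0.0494). The endothelial receptor gene TEK fell by 2.21 ± 0.39 among 14 endothelial markers (camera adjusted p = 0.919), for which the median was 0.0934 and the mean -0.127. SNAP25 fell by 0.82 ± 0.22 among 14 adipocyte and neural markers (camera adjusted p = 0.227). ACTA2 and LMOD1 fell among 11 smooth muscle markers (camera adjusted p = 0.346), and 0 of 16 epithelial and 0 of 16 leukocyte markers passed (camera adjusted p = 0.295 and 0.1). Adjusted over the list alone, 3 smooth muscle markers and 1 adipocyte or neural marker fell, 1 endothelial marker rose and 1 fell, and 0 epithelial or leukocyte markers passed.

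Of 27 lists, 12 were called, 3 higher and 9 lower, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.6. The estimated correlation also missed 1 simulated list of 50 independent genes shifted by 0.5. Correlated genes and larger shifts were not simulated, so how often this test misses lists like the real ones is unknown. Estimated correlations ran from -0.0493 (endothelial markers) to 0.612 (mitosis), and the preset was 0.01. Where the estimate lies above the preset, the p-value with the preset may be too small. In fry, which does not compare a list with other genes, 0 lists moved on balance in 1 direction (smallest adjusted p 0.16) and 22 changed when either direction counted.

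Arrays of 1 replicate were not the most alike. Across genes, which are not independent replicates, the Spearman coefficient between the arrays of a dye swap was 0.548, 0.477 and 0.0533 for replicates 1, 2 and 3 after turning. Arrays of different replicates with the same dye orientation had a mean coefficient of 0.531 (0.42 to 0.63), and those of opposite orientation 0.281 (0.0936 to 0.494). The replicate means had Spearman coefficients of 0.57, 0.55 and 0.481 with each other. In a fit of all 6 arrays, 0 genes had a dye effect past the threshold in limma, with 2262 at an unadjusted p under 0.05 and a smallest adjusted p of 0.141. By sign after turning, 1012 genes followed the dye, with 1 sign on the 3 arrays of 1 orientation and the opposite on the others. Independent signs would give about 476. That this count equals the number of genes that passed is a coincidence. Over single probes, 1000 of 21794 passed, 416 higher and 584 lower, of which 130 lay among the 4360 probes without 1 gene name.

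**Figure D3:**
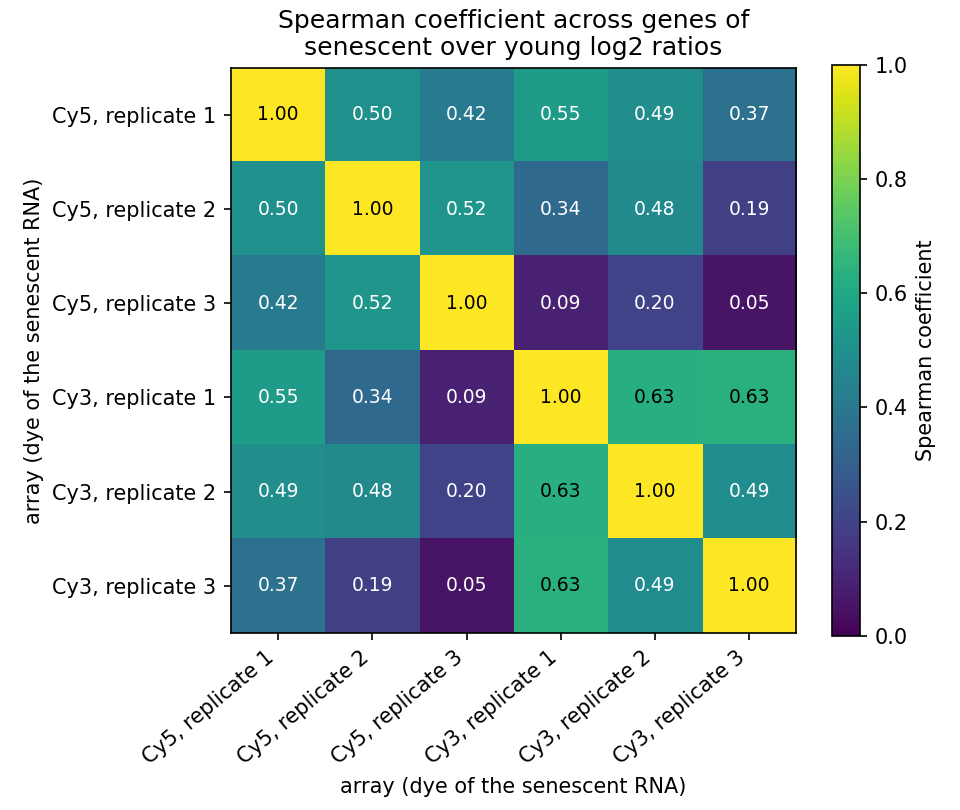
Spearman coefficient across genes between the 6 arrays after every ratio was turned to senescent over young (both axes: arrays, named by the dye of the senescent RNA and the replicate; colour: coefficient). The arrays of the replicate 3 dye swap have a coefficient of 0.0533, against 0.548 and 0.477 for replicates 1 and 2.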

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

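Leaving out dim probes and the agreement between arrays under other coefficients were chosen after the data were seen. The 1012 genes became 1784 with quantile normalization, 2470 with the replicate block, 2896 with the arrays as independent, 2527 without the noisiest probes, 2196 without dim probes and 2556 at an adjusted p under 0.1. They became 27 on the arrays with senescent RNA in Cy5, 0 on those with it in Cy3 (4228 at an unadjusted p under 0.05 in limma), 0 at an adjusted p under 0.01 and 1 in a per-gene test without moderation (2826 at an unadjusted p under 0.05). Leaving out 1 replicate gave 0 to 375 genes, with 0 without replicate 1 and without replicate 2. The 1000 probes became 2029 with quantile normalization, 3099 with the replicate block, 3577 with the arrays as independent, 1516 with robust empirical Bayes, 3241 without the noisiest and 2749 without dim probes. They became 0 on the arrays of either orientation alone, and 0 to 315 on leaving out 1 replicate. Centring, scaling, robust empirical Bayes, other rules for several probes and a 1.5-fold minimum left the gene count between 982 and 1439. The fits with the replicate block and with the arrays as independent took both arrays of a dye swap as separate observations. Their larger counts thus do not rest on more biological replicates. The cause of the differences in counts was not tested. Of the 1012 genes, 987 also passed with the replicate block, 985 with quantile normalization and 287 without replicate 3. The 12 lists became 0 with the estimated correlation (smallest adjusted p 0.6) and 0 with fry (0.16), and lay between 10 and 15 otherwise. On the Cy5 arrays the extracellular matrix, contractile, ribosomal protein and fibroblast marker lists lost their call. The antioxidant, proteasome, chaperone and leukocyte marker lists were called under some of the alternatives. The dye effect passed for 0 genes, and for 0 to 1 on leaving out 1 replicate, where the arrays were fitted as independent; without replicate 2 it was 1. The replicate block had a consensus correlation of -0.134. Of 84 named genes that passed, 7 lost their call with arrays scaled to one spread, 3 with quantile normalization and 2 with the replicate block. Without replicate 3, 32 lost it, and without replicate 1 or without replicate 2, all 84 did. On the Cy5 arrays alone 70 lost it, and on the Cy3 arrays alone 83 did and 1 reversed. The gene PSMB10 turned to 1.25 on the arrays with senescent RNA in Cy3. The mean Pearson coefficient of the dye swaps was 0.223, and 0.437 without dim probes, 0.121 without replicate 1, 0.189 without replicate 2 and 0.359 without replicate 3. The alternative for missing values was not run, since the table holds 0 missing values. Signal over background was not used here, so the limit it sets is unknown.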

Other observations

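Replication-dependent histone genes, which lie in clusters and are transcribed mainly in S phase, went both ways. Of 30 measured, 7 rose, 9 fell and 14 did not pass. Linker histone genes H1-3 (-1.82 ± 0.65), H1-4 (-1.31 ± 0.03) and H1-1 (-0.97 ± 0.38) fell while H1-2 rose (1.38 ± 0.65). Among H2A genes, H2AC6 (2.26 ± 0.45), H2AC11 (0.67 ± 0.06) and H2AC25 (0.66 ± 0.17) rose, and H2AC14 (-1.70 ± 0.38) and H2AC16 (-1.46 ± 0.06) fell. Of 5 H2B genes, H2BC21 and H2BC14 (1.20 ± 0.32) rose and 0 fell. Of 4 H3 genes, H3C12 (-1.59 ± 0.14) and H3C11 (-0.63 ± 0.10) fell and 0 rose, and among 8 H4 genes H4C3 and H4C1 (-1.45 ± 0.21) fell while H4C8 rose (1.43 ± 0.55).

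Tests of the dye effect, the histone genes and the chromosomes were chosen after the results were seen, as were the regression, the interval of the dim-probe test and the gap without replicate 3 given below.

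Opposite changes of clustered histone genes were weighed first. Signal shared by all probes of a family would give 1 direction per family, but 3 families (H1, H2A and H4) held genes called in both. The called genes of H2B and of H3 went 1 way. Signal shared between some probes of a family stays open, because probe sequences were not compared. Fewer cells in S phase would lower clustered histone genes, so it does not account for the 7 that rose. For the 9 that fell it stays open, because no measure of S phase was used here. The DNA replication list had a median of -0.875 and was called lower with the preset correlation. It was not called with an estimated correlation (camera adjusted p = 0.6). That test also missed a simulated list of independent genes with a shift of 0.5. Correlated genes and larger shifts were not simulated, so what its result means for this list is not settled. A candidate explanation of the rise, not tested, is polyadenylated histone RNA of non-dividing cells, and the primer of the reverse transcription is not given.

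Arrays of different replicates with the same dye orientation correlated more closely (mean Spearman 0.531) than the dye swaps of 1 RNA pair (0.36), but the gap rested mostly on replicate 3: without it the means were 0.566 and 0.513, and the gap 0.053 in place of 0.172. The arrays of replicate 3 had the largest SDs, 0.876 and 1.01, against 0.481 to 0.722 for the others. The median absolute deviation of its dye component was 0.324, against 0.174 and 0.128 for replicates 1 and 2. Its array titles also carry codes of another form, whose meaning is not given. Whether a technical difference of replicate 3 gave the gap was not tested. A gene-specific dye effect may contribute, but the test could not decide it. The dye components, the part of the ratio that does not turn with the swap, correlated between replicates at 0.27, 0.396 and 0.353. After regression on the mean senescent over young ratio the coefficients were 0.283, 0.393 and 0.377. They restate that, between replicates, arrays of the same orientation were more alike than those of opposite orientation (0.531 against 0.281). They are therefore no separate support. A single array with senescent and young exchanged was argued against by the mitosis list, whose median was below 0 on all 6 arrays (highest -0.744). The list cannot show an array assigned to the wrong replicate, so that stays open. Without dim probes 78.4% of the gap was left, above the bound of 75 set before. Over 100 resamples of genes the share ran from 68.5 to 85.4, which includes the bound. The genes with and without dim probes were drawn separately, although they overlap. Resampling genes also does not measure the spread between arrays. Dim spots therefore stay open as part of the gap.

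The late passage might carry a gained or lost chromosome. No shift was seen: over 22 autosomes with 14626 genes, chromosome medians ran from -0.0439 to 0.0462, 0 had an unadjusted p under 0.05 in camera, and the smallest adjusted p was 0.982. A change in a small share of cells stays open.

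In the fit of 6 independent arrays, 1 of the 10 splits into 3 and 3, the real one, gave as many as 2896 genes, and the highest other gave 0. With 10 splits, a share under 0.05 cannot be reached. In the other splits the difference between senescent and young cells stays in the residual spread, which makes calls less likely. Their 0 is therefore no measure of calls by chance. The splits also ignore that the arrays form dye-swap pairs and are not independent, and the fit of the 3 replicate means called 1012 genes.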
